A study of Rattus norvegicus with 8 samples.

How the data were processed

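Total RNA was extracted from bilateral 1 mm3 cryostat micropunches of the dorsal hippocampus of drug-naive, young adult, first-generation male Sprague-Dawley rats. Per the labels, biotinylated cDNA was hybridised to Affymetrix arrays, 1 array per litter. The 8 arrays fall into 4 from sons of sires that took nicotine themselves (0.03 mg/kg intravenously, for 60 days) and 4 from sons of yoked saline sires, called nicotine-sired and saline-sired below. Each array comes from a different father, so the replicates are biological.

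The deposited value table holds log2 signals for 36685 probe sets per array, and the authors' deposited analysis table repeats the same log2 values, with a largest difference of 0. The submitters' processing notes name MAS5 with no version. Which summary and normalization made the log2 values, the array model and the scan dates are not given in the sources used here. Per the file headers, the authors' deposited table also holds a p-value, a step-up adjusted p-value, a linear ratio of nicotine over saline and a signed fold score. The deposited adjusted p-value equals a Benjamini-Hochberg adjustment over all rows to within 1.98e-06, and the deposited ratio equals 2 to the power of the difference in mean log2 to within 8.09e-05. The signed fold score of the authors is that ratio where it is above 1 and minus its inverse where it is below. The model behind the authors' p-values is not given in the sources used here.

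Of the probe sets, 30323 belong to gene classes and 6362 to control classes, which were left out of the tests. By the annotation in the files, 20318 gene-class probe sets had 1 gene symbol, 1932 had several and 8073 had none. Annotation cells ended at 255 characters, so the last record of the 10854 cells of that length was not used. Symbols were updated by gene ID with RefSeq names of the GRCr8 assembly, which held 19426 of the probe sets with 1 symbol and renamed 3522. No coordinates of that assembly are given, since the annotation in the files cites another build. Probe sets with several symbols were not named.

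The values were already log2, so no pseudocount was added. Without detection calls, probe sets were kept when their mean over all 8 arrays was above the median gene-class probe set, which left 15161. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over the kept probe sets. Adjusted p-values below come from that fit unless another source is named, and errors after differences are its standard errors. A fixed set of 34 gene lists, of which 33 had at least 5 measured genes, was tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (12320 genes). The list of blood markers had too few measured genes and was not tested. Calls were repeated with a correlation estimated per list and with fry. Single values were compared by exact permutation over the 70 assignments of the arrays to groups of 4, whose smallest two-sided p is 0.0286. The number of arrays limits the precision of every value.

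On simulated arrays with the real means and spreads, 200 of the 15161 probe sets were changed and noise was drawn independently for each probe set. The fit of nicotine-sired against saline-sired recovered 91.2% of changes of 1 log2 unit and 98.9% of changes of 2 log2 units, with 5.44% false calls over 20 draws. On the real arrays genes vary together, with a median estimated correlation within lists of 0.23. These rates therefore need not hold for the real arrays.

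The lists, tests and named genes were fixed before the data were examined. The plan was written knowing of a gene that the published study of these animals follows up. That gene was chosen on these same samples and is a CA1 marker, so it is not independent evidence in the CA1 list. Named genes were the 12 higher and the 12 lower genes with the smallest p among probe sets with 1 symbol whose groups did not overlap, whether or not they passed; in each list the 3 members with the smallest p, and in each called list the 4 with the smallest p in its direction; the 3 highest and the 3 lowest folds of the authors' deposited table among probe sets with 1 symbol; and Chrna4, Chrna7 and Chrnb2. Alternatives covered pseudocounts on back-transformed values, filters, quantile normalization, median centring, the litter number as a block, array weights, eBayes without a trend and each array left out. The fits without the 2 arrays highest in Ttr and with a CA1 marker covariate were added after seeing the data. Some genes that the rule names are not reported here. Actin, Gapdh and hexokinase 3'/5' ratios were not analysed here.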

Results

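Gene expression was measured in dorsal hippocampal punches of 8 drug-naive male rats, 4 nicotine-sired and 4 saline-sired. The comparison asks whether a father's nicotine taking is accompanied by a different hippocampal transcriptome in sons that never received the drug. Median gene-class signals ran from 6.25 to 6.35 log2 units across arrays. The median difference over the 15161 kept probe sets was 0.02.

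Cfap43, Dnah6 and Ak7, genes of motile cilia, were among the transcripts with the smallest p that were higher in nicotine-sired sons, and the potassium channel genes Kcnc2 and Kcnh8 among those that were lower. Cfap43, which encodes a protein of the ciliary axoneme, rose by 1.50 ± 0.16 log2 units (2.83-fold, adjusted p = 0.0196, n = 4 per group). Fxyd7, a regulator of the sodium pump in neurons, fell by 0.91 ± 0.09 (1.88-fold, adjusted p = 0.0196). In all, 313 probe sets passed an adjusted p of 0.05, 179 higher and 134 lower, covering 166 and 116 named genes. At an unadjusted p under 0.01 there were 1452 (903 higher, 549 lower), against 151.6 expected by chance. The groups did not overlap in 14.3% of kept probe sets, where chance gives 2.86%.

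The count of adjusted calls changed with single arrays. By limma it was 0 without saline-sired 1 and 0 without saline-sired 3, with 2724 and 2932 probe sets at an unadjusted p under 0.05. It was 8 without saline-sired 2, 70 without saline-sired 4, 80 without nicotine-sired 1, 98 without nicotine-sired 3, 672 without nicotine-sired 2 and 737 without nicotine-sired 4. The count at an unadjusted p under 0.01 moved by over 1.5 times without saline-sired 1 (868) and without saline-sired 2 (955). In place of 179 higher and 134 lower calls, lower calls were the more frequent with each array centred on its median (155 and 192), with a stricter filter (82 and 99) and without nicotine-sired 1 (31 and 49). Without nicotine-sired 3 there were 71 higher and 27 lower calls.

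The 12 higher genes named by the rule all passed. Besides Cfap43 they held Dnah6, an axonemal dynein heavy chain, which rose by 1.19 ± 0.15, and Ak7, an adenylate kinase of cilia, which rose by 1.45 ± 0.19. Spata18 rose by 1.39 ± 0.16, and Gfra2, the receptor of neurturin, by 1.13 ± 0.15. Bgn, the proteoglycan biglycan, rose by 0.60 ± 0.07. Iqck, Lrrc34, Akd2, Zfp488 and C16h10orf53 rose by 0.55 to 1.23. Dnah6 and Akd2 were dim on the saline-sired arrays, with means of 6.08 and 6.09, under the filter value of 6.30. The sizes of their rises are therefore less sure. Ftl1l5, a ferritin light chain copy whose probes may match paralogs, rose by 0.42 ± 0.06.

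The 12 lower genes all passed as well. Kcnc2, a fast potassium channel of interneurons, fell by 0.61 ± 0.07, and Kcnh8, another potassium channel, by 1.03 ± 0.14. Rimbp2, a scaffold of the presynaptic active zone, fell by 0.47 ± 0.07. Hcrtr2, an orexin receptor, fell by 0.97 ± 0.14, and Camkk1, a kinase upstream of calmodulin kinases, by 0.57 ± 0.07. Kcnh8 and Hcrtr2 were dim on the nicotine-sired arrays, with means of 6.09 and 6.24, under the filter value of 6.30. The sizes of their falls are therefore less sure. Dpyd, Slc7a14, Mblac2, Rac3 and Ano3 fell by 0.87, 0.68, 0.49, 0.48 and 0.39.

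**Figure D1:**
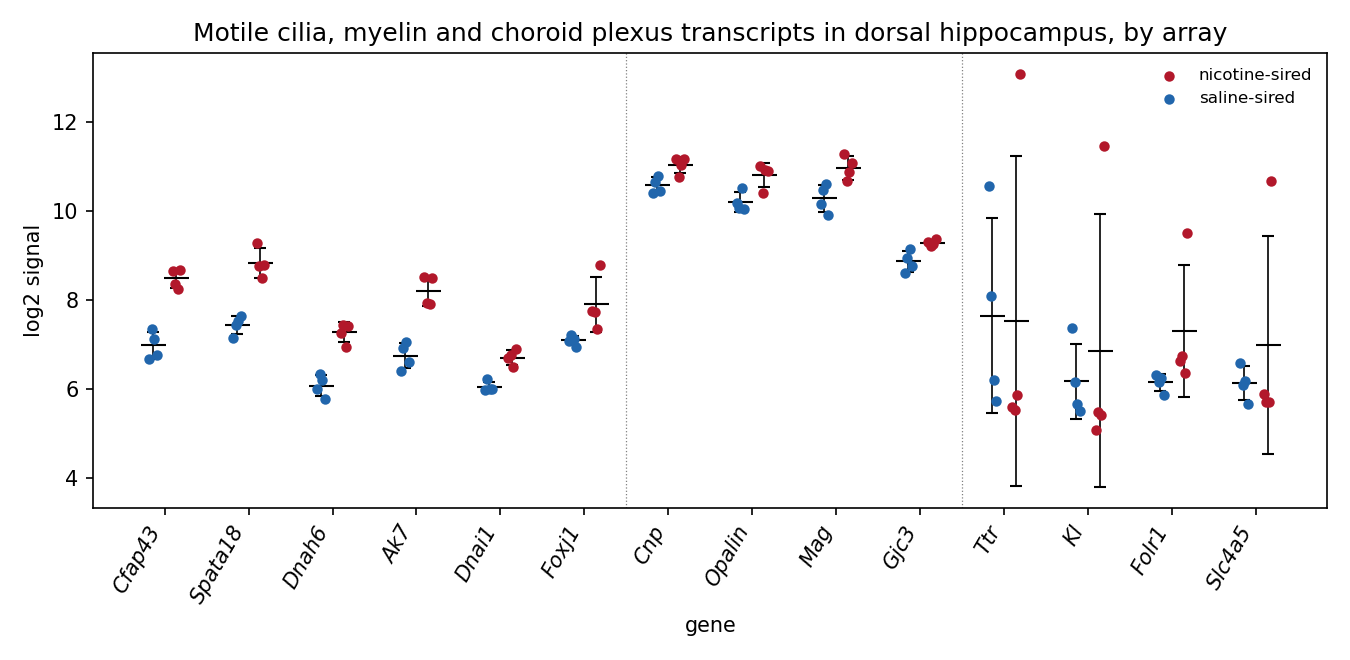
Log2 signal (vertical axis) of motile cilia, myelin and choroid plexus genes (horizontal axis, in that order, parted by dotted lines) on each array; bars give the mean and SD of 4 arrays. Cfap43 lay at or above 8.24 on the nicotine-sired arrays and at or below 7.34 on the saline-sired arrays, whereas Ttr reached 13.07 on nicotine-sired 4 alone in its group. The choroid plexus genes and Dnai1 were chosen for display after their values were seen.

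Markers of CA1 pyramidal cells lay higher. All 9 measured CA1 markers were higher in nicotine-sired sons, with a median of 1.78, and 9 of 9 passed when adjusted over the list alone, but 1 of 9 over all probe sets. That 1 was Dcn, which rose by 2.11 ± 0.41 (adjusted p = 0.0398) and is also a fibroblast marker. Ndst4 was higher by 2.05 ± 0.50 and Mpped1 by 1.74 ± 0.44, with adjusted p-values of 0.0642 and 0.0698. The mean score of 8 CA1 markers overlapped between the groups, at -0.10 on nicotine-sired 4 and -0.025 on saline-sired 4. The camera call of the CA1 list (adjusted p = 9.11e-06) was lost with an estimated correlation (adjusted p = 0.658). Markers of dentate granule cells lay lower, 11 of 12 of them, with a median of -0.49, and 0 of 12 passed over the list alone or over all probe sets. Trpc6 differed by -0.81 ± 0.24 and Prox1, the granule cell transcription factor, by -0.99 ± 0.34. The mean dentate score differed by -0.51 (exact permutation p = 0.0857) and rested in part on nicotine-sired 1. Without that array it differed by -0.29, the list median was -0.33 and Prox1 differed by -0.60. The dentate call (camera adjusted p = 0.000416) was lost as well (adjusted p = 0.658 with an estimated correlation).

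**Figure D2:**
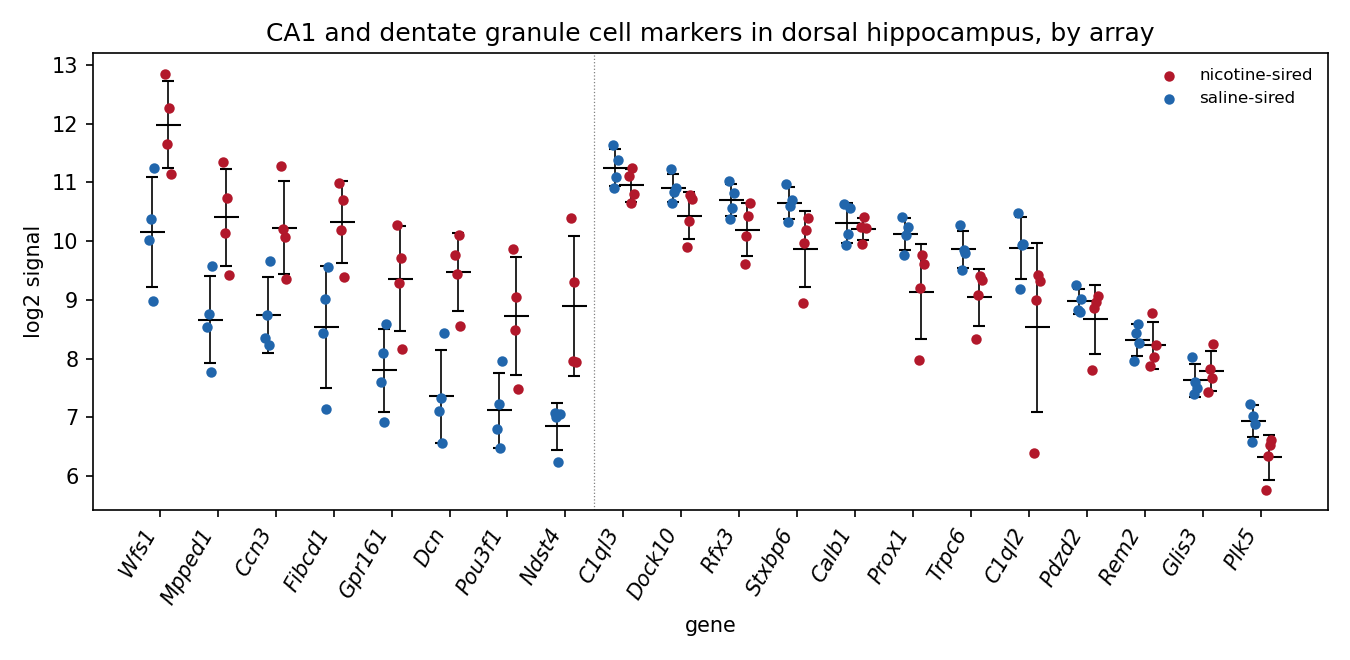
Log2 signal (vertical axis) of 8 CA1 markers, left of the dotted line, and dentate granule cell markers, right of it (horizontal axis), on each array; bars give the mean and SD of 4 arrays. For 6 of the 8 CA1 markers nicotine-sired 4 lay below saline-sired 4, whereas Dcn ran from 8.56 to 10.11 on nicotine-sired arrays and from 6.56 to 8.44 on saline-sired arrays, and C1ql2 was lowest, at 6.40, on nicotine-sired 1.

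Glial and vascular markers tended higher. All 22 measured oligodendrocyte and myelin genes were higher, with a median of 0.45; 18 passed when adjusted over the list alone and 0 over all probe sets. Mag, a myelin adhesion protein, was higher by 0.69 ± 0.17 and Cnp by 0.46 ± 0.11. All 12 markers of oligodendrocyte precursors were higher (median 0.27), 7 past the threshold adjusted over the list alone and 2 over all probe sets, where Gpr17 rose by 0.51 ± 0.08 and Vcan by 0.42 ± 0.08. All 23 endothelial and pericyte markers were higher (median 0.24), 13 adjusted over the list alone and 1 over all probe sets, the pericyte gene Rgs5 (0.39 ± 0.07). Of 22 microglial markers 20 were higher (median 0.24, 4 adjusted over the list alone), and of 23 astrocyte markers 19 (median 0.14, 5 adjusted over the list alone), with 0 past the threshold over all probe sets in either list. Inflammation and interferon genes were higher in 17 of 20 (median 0.26, or 0.16 without nicotine-sired 3), and Rela, a subunit of NF-kappa-B, rose by 0.43 ± 0.07. Choroid plexus and ependymal genes were higher in 13 of 15 (median 0.68), and the ciliary gene Enkur rose by 1.12 ± 0.20 and Tmem212 by 0.68 ± 0.13. Without nicotine-sired 4 the median of that list turned to -0.086. The camera calls of these 7 lists (adjusted p from 2.36e-08 to 0.0273) were lost with an estimated correlation (adjusted p from 0.658 to 0.723).

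Genes of synaptic vesicle release lay lower in 29 of 39 (median -0.14); 15 fell and 1 rose when adjusted over the list alone, and 6 fell over all probe sets. Syt4, a synaptotagmin, fell by 0.44 ± 0.07, Rph3a by 0.59 ± 0.11, Stx1a, a syntaxin of the release machinery, by 0.53 ± 0.10 and Syn1, which tethers vesicles, by 0.34 ± 0.07. Voltage-gated channel genes lay lower in 28 of 44 (median -0.12, or -0.037 without nicotine-sired 4), and Kcnc2 and the calcium channel subunit gene Cacnb4 (0.34 ± 0.06) fell. Oxidative phosphorylation genes lay lower in 40 of 55, with a median of -0.03 that went to -0.00018 without nicotine-sired 3 and to -0.0025 without saline-sired 4. Lipid and cholesterol synthesis genes lay lower in 18 of 25, with a median of -0.08 that went to -0.020 without nicotine-sired 1 and turned to 0.097 with a CA1 marker score as a covariate. Neither call was kept without those arrays, and 0 members of either list passed the threshold. The camera calls of these 4 lists (adjusted p from 1.85e-07 to 0.0214) were lost with an estimated correlation (adjusted p from 0.658 to 0.723).

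In all, camera called 13 lists at its preset correlation, 8 higher and 5 lower. With an estimated correlation 0 were called and the smallest adjusted p was 0.658, and fry called 0. Without nicotine-sired 4, 9 of the 13 calls were kept, and those of voltage-gated channels, inflammation and interferon, astrocytes, and choroid plexus and ependyma were lost. Without saline-sired 4, 10 were kept, and those of oxidative phosphorylation, inflammation and interferon, and choroid plexus and ependyma were lost. The calls of oxidative phosphorylation and lipid synthesis were lost without nicotine-sired 1, that of oxidative phosphorylation without nicotine-sired 3, and those of lipid synthesis and astrocytes without saline-sired 3. With the CA1 score as a covariate 7 were kept and lipid synthesis was called in the other direction. The calls of CA1 and dentate markers, oxidative phosphorylation, astrocytes and microglia were lost. The loss for CA1 markers was fixed in advance, since 8 of them form the score. Lists outside the 13, such as postsynaptic density and glutamate receptors, came to be called with that covariate. Other ways of splitting the same arrays gave up to 17 called lists, so the calls of lists do not set the real grouping apart.

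**Figure D3:**
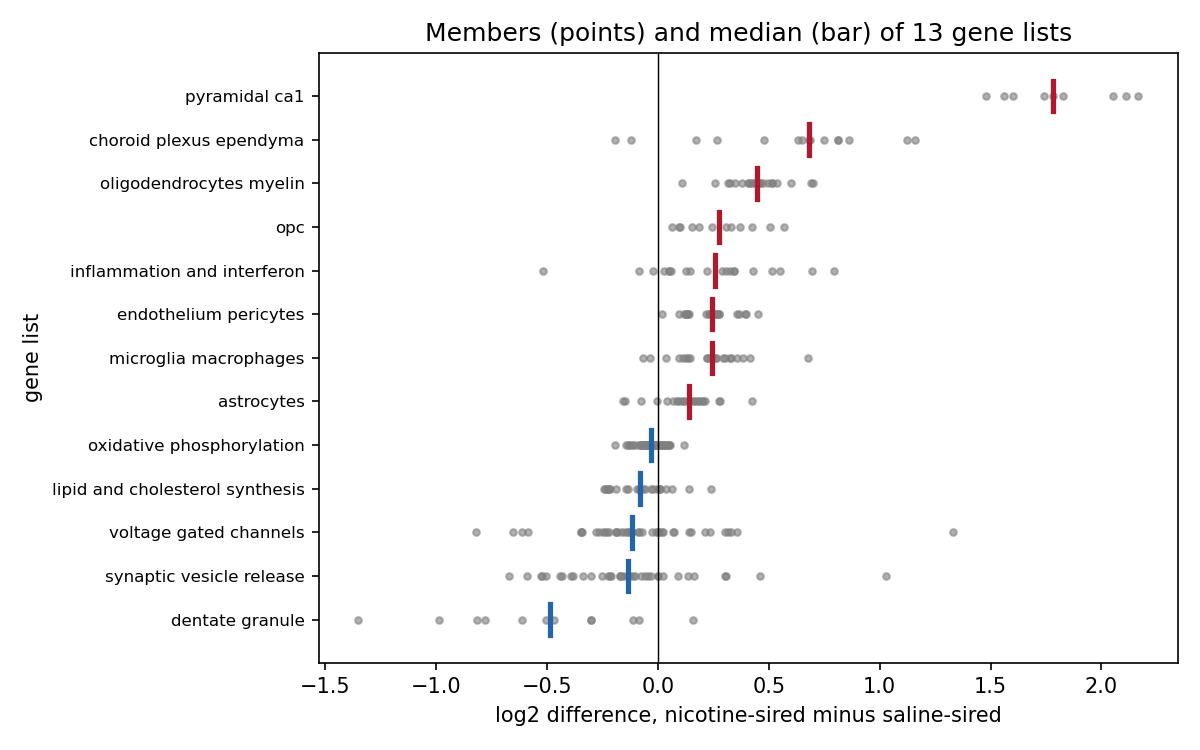
Difference in log2 signal, nicotine-sired minus saline-sired (horizontal axis), of each measured gene (points) and the median (coloured bar) in the 13 lists called by camera at its preset correlation (vertical axis). The CA1 median was 1.78 and the dentate median -0.49.

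Among genes of the drug's own receptors, Chrna7, the alpha7 nicotinic subunit, fell by 0.51 ± 0.09 (adjusted p = 0.0312 in limma, all 4 values below all 4). Chrna4 differed by 0.25 ± 0.14 (0.14 without nicotine-sired 3) and Chrnb2 by -0.07 ± 0.08, with adjusted p-values of 0.299 and 0.665. The list of nicotinic and cholinergic genes was not called (camera adjusted p = 0.765), and its median of 0.04 and camera's direction differed in sign; with each array centred on its median the list's median was -0.011. The metabotropic glutamate receptor gene Grm7 fell by 0.51 ± 0.08, whereas the list of glutamate receptors was not called (adjusted p = 0.367), with a median of 0.04, which turned to -0.013 with median centring, and a mean of -0.11. Single members of other uncalled lists also passed. Jun fell by 0.46 ± 0.09, Homer3 by 0.85 ± 0.18, Neurod1 by 0.63 ± 0.13 and Lamp5 by 1.28 ± 0.26. Hdac11 rose by 0.65 ± 0.13, Bag3 by 0.61 ± 0.11, Etv1 by 0.48 ± 0.08 and Maob by 0.37 ± 0.08.

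With the mean score of 8 CA1 markers as a covariate, a fit added after seeing the data, none of the named genes passed. Standard errors grew by a median ratio of 1.59 over the 44 named genes outside the score that had passed, and all 44 kept their direction. Of these, 33 kept their difference to within a factor of 1.5 or had a larger one, and 16 of the 33 had one as large or larger. Cfap43 differed by 1.64 ± 0.27, Dnah6 by 1.50 ± 0.22, Kcnc2 by -0.66 ± 0.12 and Chrna7 by -0.58 ± 0.15. The other 11 moved toward 0 by more than 1.5 times. Gfra2 differed by 0.70, Hdac11 by 0.28, Bag3 by 0.26, Etv1 by 0.25 and Rgs5 by 0.20, and Hcrtr2 by -0.62, Lamp5 by -0.47, Homer3 by -0.39, Stx1a by -0.29, Rph3a by -0.24 and Jun by -0.19. Prox1 and Trpc6, which had not passed, each differed by -0.31. Dcn and Ndst4 are part of the score; with the score of the other 7 markers they differed by 0.70 ± 0.43 and 0.51 ± 0.70.

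As whole profiles, arrays of the same group were on average closer than arrays of different groups, with mean Pearson correlations of 0.982 and 0.972. The difference of 0.0103 was the largest of the 35 splits into 4 and 4 (exact permutation p = 0.0286). It no longer passed without saline-sired 1 (0.00652, exact p = 0.0857) or without saline-sired 3 (0.00833, exact p = 0.0571). Not every array was closer to its own group. Nicotine-sired 2 had a mean correlation of 0.9802 with its own group and 0.9808 with the saline-sired arrays, and nicotine-sired 4 had 0.9694 and 0.9690. Saline-sired arrays had 0.986 to 0.989 with their own group. Median signal over all gene-class probe sets was lower in nicotine-sired sons by a difference of -0.04 (exact permutation p = 0.0286, Benjamini-Hochberg 0.193 over 9 array measures), and none of the 9 passed the adjustment. At this smallest exact p, 1 measure alone could not pass, so that outcome does not show balanced arrays. Poly-A spike controls were higher by 0.18 (exact permutation p = 0.0571), the ribosomal RNA class by 0.32 (0.0857) and the median signal of kept probe sets by 0.05 (0.0857). The other measures had exact permutation p-values of 0.286 or more.

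The authors' deposited table calls 1763 probe sets at an adjusted p of 0.05, 841 higher and 922 lower. Among the kept probe sets it calls 1309, and these included 235 of the 313 found by limma. Both rest on the same array values but not on the same test. The authors' p-values are not those of an equal-variance 2-group test on these arrays, and 69.1% of those compared lay below it. The counts of calls are therefore not like for like. Among probe sets with 1 gene symbol, high folds in the authors' deposited table were those of Nts, which encodes neurotensin, at 6.11 and Adgrl2 at 5.01. The lowest were Slit2 at -3.39, Mei1 at -3.35 and Plcxd2 at -3.17. In limma these 5 genes did not pass, with adjusted p-values from 0.0557 to 0.133. With the CA1 covariate the log2 difference of Nts went from 2.61 to 0.26 and that of Adgrl2 from 2.32 to 0.48, and Slit2 and Mei1 changed sign (0.13 and 0.16). Without nicotine-sired 1 the log2 difference of Slit2 went from -1.76 to -1.05 and that of Plcxd2 from -1.66 to -1.04. The lowest fold of all gene-class probe sets in the authors' deposited table, -11.92, belonged to a probe set with no gene symbol, singled out after its values were seen. It read 3.50 to 3.87 on nicotine-sired 1 to 3, below the antigenomic background of those arrays (5.06 to 5.14), so its fold has no exact size. On nicotine-sired 4 it read 7.21, near the 7.82 to 8.65 of the saline-sired arrays.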

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

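All tests of explanations here, and the lists of motile cilia genes and of choroid plexus genes alone, were chosen after the results were seen. Of 154 groups of 4 arrays examined, 12 held an array far from the other 3, where chance gives about 1 in 20 (7.7), and 6 of the 12 were on nicotine-sired 4. The 154 groups share genes, and choroid plexus genes on nicotine-sired 4 count in more than 1 list. The 12 are therefore not independent, and 12 against 7.7 is no test of chance.

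On nicotine-sired 4 the mean centred score of choroid plexus and ependymal genes was 2.33, against at most -0.34 on the others of its group. The score of choroid plexus genes alone was 3.11, that of striatal and septal genes 1.56, that of meningeal genes 1.16 and that of astrocytes 0.15. Mei1 stood at 7.75 there. Ttr, the most abundant choroid plexus transcript, read 13.07, while saline-sired 1 read 10.55 and saline-sired 2 read 8.08. Tissue from outside the hippocampus on that array stays open: the smaller gap of its choroid plexus and striatal scores to the next array was 1.69, but these scores prompted the explanation and cannot test it. An exchange with saline-sired 4 is argued against, since exchanging them left 548 probe sets at an unadjusted p under 0.01 in place of 1452. The sires' treatment as a source of these transcripts on a single array was not tested.

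The CA1 markers, higher with dentate markers lower, form the next pattern. A difference in array scale is argued against, since the median kept probe set differed by 0.017 and the CA1 median was 1.78. A larger share of CA1 tissue in the nicotine-sired punches stays open: with the CA1 score as a covariate the dentate score difference went from -0.51 (exact permutation p = 0.0857) to -0.069 ± 0.41, with a 95% interval from -1.11 to 0.98 that is too wide to decide. An effect of the sires' nicotine on CA1 genes at an unchanged tissue share cannot be told apart from it, since the 9 markers differed by nearly even amounts (SD 0.25), which a shared regulator could also give.

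Of 35 measured motile cilia genes 34 were higher and 16 rose past the adjusted threshold (median 0.81). Choroid plexus in the punches is argued against, since without nicotine-sired 4 the median of choroid plexus genes was -0.25 and that of cilia genes 0.61. The same CA1 difference is argued against for cilia genes, whose score differed by 0.77 without and by 1.07 with the CA1 covariate (95% interval 0.48 to 1.66). For myelin it stays open: the score difference went from 0.44 (exact permutation p = 0.0571) to 0.59 with the covariate, not toward 0, but the interval of -0.04 to 1.23 holds 0. More ependyma in the punches and an effect of the sires' nicotine were not tested and could both remain, as the value of 1.07 decides between neither.

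The other values far from their group were the DNA methylation machinery score of nicotine-sired 2 (-0.0099), the median gene-class signal of nicotine-sired 1 (6.25), and the exon control mean (9.27) and antigenomic background (4.997) of saline-sired 1. Chrna4 stood at 6.80 on nicotine-sired 3 and Chrnb2 at 10.40 on saline-sired 2.

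The real split gave the highest counts of probe sets but not of lists. With 35 splits the share of splits cannot go below 0.0286. Chance is therefore argued against for the counts of probe sets, but it is not excluded. Of the 35 splits of the 8 arrays, 1, the real one, gave 313 adjusted calls, and the highest other gave 1. For an unadjusted p under 0.01, again 1 split gave as many as 1452 and the highest other gave 548. For gene lists, 11 of the 35 splits gave 13 or more, and the highest other gave 17.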

How the results depend on the processing

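The fits without high Ttr arrays and with the CA1 covariate were added after seeing the data. The 313 adjusted calls became 155 with no filter, 181 with the stricter filter, 1201 with array weights, 4 without the 2 high Ttr arrays, 0 with the CA1 covariate (1517 at an unadjusted p under 0.05 in limma) and 2062 with the p-values of the authors' deposited table. They ranged from 0 to 737 with each array left out. The count at an unadjusted p under 0.01 became 778 with the stricter filter, 378 with the CA1 covariate and 2420 with the authors' deposited p-values, and ranged from 868 to 1656 with each array left out. The 13 lists became 0 with an estimated correlation and 0 by fry. Of the 13 calls of lists 11 were kept with no filter, 11 with the stricter filter, 12 with quantile normalization and 12 with array weights. It was 9 without the high Ttr arrays and 7 with the CA1 covariate, where 1 more, lipid synthesis, was called in the other direction. Camera called 13 lists in all with that covariate, of which 8 were among the 13 of the main fit and the rest were new. No filter tested more probe sets (30323), the stricter filter fewer (7581), and the left-out settings had fewer arrays; otherwise the cause was not tested.

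The distance between groups ranged from 0.00652 to 0.0139 with each array left out and was 0.0110 without the high Ttr arrays, where 3 against 3 cannot go below an exact permutation p of 0.1. The choroid plexus and ependyma median ranged from -0.086 (without nicotine-sired 4) to 0.93 with each array left out, and was -0.022 without the high Ttr arrays.

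Of 2504 values of 134 genes taken by the naming rule, 2050 under the alternatives kept their side of the threshold and their direction. Another 346 no longer passed, 96 came to pass and 12 changed sign. Genes that had not passed could not lose the threshold, and only 44 of the 131 genes outside the CA1 covariate had passed. The 2050 values therefore do not measure how often a call was kept. With the CA1 covariate these genes changed sign, none of them past the threshold there or before: Chrm5 (-0.18), Homer2 (-0.11), Irf9 (-0.056), Hmgcs1 (0.073), Insig1 (0.099), Mpped1 (-0.062), Cck (-0.038), Slc17a6 (-0.15), Trpc4 (-0.37), Slit2 (0.13) and Mei1 (0.16). Mpped1 is itself part of that covariate. Of the 131 genes outside it, 45, of which 11 had passed before, kept their sign but moved toward 0 by more than 1.5 times. Another 76, of which 33 had passed, kept their difference to within that factor or had a larger one. None passed with the covariate, where standard errors grew by a median ratio of 1.58. Chrnb2 ranged from -0.13 to 0.00063 with each array left out.

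Medians of list values that changed sign lay near 0 in most cases. Besides lipid synthesis, the lists of postsynaptic density and glutamate receptors were called by camera with the CA1 covariate (adjusted p = 0.00406 and 0.0226). Neither was called in the main fit. With the CA1 covariate they were 0.29 for CA2 and CA3 markers, -0.19 for cholinergic genes, -0.025 for monoamine and opioid genes, -0.15 for glutamate receptors, -0.12 for postsynaptic density, 0.097 for lipid synthesis, -0.011 for ribosomal proteins, 0.12 for neurogenesis, -0.038 for immediate early genes, 0.014 for neurotrophin signalling, -0.016 for the circadian clock, -0.040 for inhibitory neurons and -0.062 for the CA1 markers that form the covariate. With median centring they were -0.011 for cholinergic genes, -0.046 for monoamine and opioid genes, -0.025 for the stress axis, -0.013 for glutamate receptors, -0.031 for ribosomal proteins and -0.00017 for thalamus and habenula. Quantile normalization gave -0.032 for monoamine and opioid genes and -0.0013 for the stress axis, and a pseudocount of 64 gave 0.0062 for CA2 and CA3. For cholinergic and for monoamine and opioid genes, no filter gave -0.053 and -0.054, and the stricter filter -0.035 and -0.029. Without the high Ttr arrays the medians were -0.018 for monoamine and opioid genes, -0.014 for ribosomal proteins, 0.039 for neurogenesis and -0.060 for striatum and septum. With each array left out the ranges were -0.16 to 0.056 (CA2 and CA3), -0.059 to 0.19 (cholinergic), -0.056 to 0.049 (monoamine and opioid), -0.015 to 0.071 (glutamate receptors), -0.0049 to 0.056 (ribosomal), -0.00077 to 0.11 (thalamus and habenula), -0.027 to 0.033 (neurogenesis) and -0.061 to 0.70 (striatum and septum).

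With the litter number as a replicate block, limma called 0 probe sets (3326 at an unadjusted p under 0.05), 1137 at an unadjusted p under 0.01 and 13 lists. Whether the numbers pair the samples, as yoked sires could, is not known. Deviations of same-numbered arrays correlated at -0.14, 0.18, -0.05 and -0.17, and 1 of 4 nicotine-sired arrays correlated best with its own number. These values show no clear pairing, but 4 pairs are too few to exclude it. The block fit therefore stays a possible reading. The authors' deposited table holds the same array values, so only its p-values served as an alternative. No scan date was given, so none could be used. Antigenomic background probe sets averaged 5.09 and 5.11 in nicotine-sired and saline-sired arrays and the median gene-class probe set 6.28 and 6.32, so dim probe sets lay near background.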

Other observations

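Beyond the lists above, circadian clock genes were higher in 16 of 20 (median 0.08, camera adjusted p = 0.0723), and 4 passed when adjusted over the list alone. Npas2 was higher by 0.88 ± 0.22 and Bhlhe41 by 0.49 ± 0.12, with adjusted p-values of 0.0662 and 0.0709 over all probe sets. With the CA1 score as a covariate they differed by 0.081 and 0.090 (adjusted p = 0.912 and 0.865). Genes of the DNA methylation machinery were higher in 14 of 15 (median 0.10, or 0.063 without nicotine-sired 3, camera adjusted p = 0.108), with Tet1 at 0.28 ± 0.07. Htr1b, a serotonin receptor gene, was higher by 2.06 ± 0.45 (adjusted p = 0.0542), and by 0.26 with the CA1 covariate (adjusted p = 0.723).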
